A study of Homo sapiens with 12 samples.

How the data were processed

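RNA from 12 samples of HaCaT cells, 3 for each of 4 treatments, was sequenced. Whether the 3 samples of a treatment were separate cultures is not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a dual-mode mRNA kit (Hieff NGS MaxUp). Per the submitters' processing notes, fastp and HISAT2 were used with the genome build hg38, without versions. The counting program, the annotation release and the strand setting are not given in the sources used here. The deposited table holds 20263 Ensembl genes and 36 value columns, 3 per library. Per the file headers these are a count, a TPM and an FPKM value for each gene. The deposited count values are whole numbers, the deposited TPM columns sum to 999950 to 999969, and the deposited FPKM columns were not used. All 36 columns were matched to a library by the labels' names. Coordinates are those of the deposited table. Gene symbols are those of the table. A list of current gene names held 20148 of the gene IDs and gives other symbols for some (RIGI for DDX58, WARS1 for WARS, CCN1 for CYR61), and 17 symbols stand on more than 1 gene ID.

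The libraries held 38.3 to 47.9 M counts (M, 1e6), 15382 to 15599 genes with a count, and 7.45 to 9.36% of counts in 13 mitochondrial genes, with the highest shares in TNF replicate 2 (9.24%) and MoCe_TNF replicate 3 (9.36%). No 2 libraries were identical, and 2586 genes had no count in any library. Averaged over genes, replicate pairs differed more than counting alone gives, with a chi-square per degree of freedom of 20.7 to 39.6. A few genes with a large spread can set this average, so it does not describe each gene. The biological coefficient of variation was 13.8%, and TMM factors ran from 0.977 to 1.03.

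Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (14109 tested), scaled with TMM, and fitted with the quasi-likelihood method on all 12 libraries with 1 mean per group, leaving 8 residual degrees of freedom. The comparisons were TNF against PBS, MoCe against PBS, MoCe_TNF against TNF, MoCe_TNF against MoCe, and the interaction, which is the TNF-α response after pretreatment less that without it. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are the fitted values and their SE was derived from the same test. CPM values were computed with the TMM-scaled library sizes.

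Gene lists were tested with camera of limma 3.58.1 with the correlation between genes preset at 0.01, adjusted over the lists with at least 5 members tested. Of 48 lists with 1138 entries, of which 1136 matched the table, 44 could be tested. Some lists share members, so their calls are not independent. For example, TAP1 and TAP2 stand in both the interferon gamma response and the antigen presentation list. Camera with the correlation estimated from the data and fry were run beside it. Members were counted as higher or lower with p-values adjusted over all genes tested, and again adjusted over the list alone. A list can be called when few of its members pass, because camera compares it with the other genes.

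The tests, the lists, the comparisons and the rule for naming genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls of a comparison (5 and 5 for the interaction) among called genes with at least 5 CPM in the higher group and, except for the interaction, no overlap between the groups. It adds the 4 members with the smallest p-values of each list described, and 25 genes of the TNF-α and interferon responses whatever their values. Not every gene that the rule takes is printed. Of the genes printed, ALDOC, C3, IFNAR2, IRF9, PDGFRA, PRRG1, TAP2, TMEFF1, TOMM6, UBD and UGT1A8 overlap another gene on their strand by the coordinates of the deposited table, which makes their counts uncertain. ACAT2, CCND1, CRYZ, CXCL10, CXCL11, CXCL16, DOCK8, GPRC5B, IFIT1, IFIT3, IRF1, KIF20A, PRDM1, SAMD11, SERPINB3, SOD2, TAP1, TNFRSF10B, TP53INP2, VWA5B2 and WARS overlap a gene on the opposite strand only, and their counts are as uncertain if the counting did not use strand. Of the 25 genes, IFNB1 had no count.

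The alternatives were chosen at the same time. They were size factors of DESeq2 1.42.0 in edgeR, the DESeq2 Wald test, no filter on low counts, only the libraries of the groups compared, the replicate number as a block, a 2-fold minimum, limma trend on log2(TPM + 1) for 12584 genes with at least 1 TPM in 3 libraries, and each library left out in turn. Genes for which DESeq2 gave no adjusted p were not counted as called. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

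The procedure was tested on simulated data with 50 genes changed at each of 4 sizes. Counts were drawn once per comparison, with a spread that followed the trend over expression and none particular to a gene. The shares recovered and falsely called may therefore differ in the real data. For TNF against PBS it recovered 100% of 4-fold, 84% of 2-fold, 54% of 1.5-fold and 10% of 1.25-fold changes among 13990 genes. For MoCe against PBS the shares were 98, 92, 64 and 16% (13980 genes), for MoCe_TNF against TNF 100, 96, 54 and 12% (13975 genes), and for MoCe_TNF against MoCe 100, 92, 56 and 4% (13991 genes). For the interaction they were 100, 62, 18 and 2% (14000 genes), so most differences of response of 1.5-fold or less were missed. The share of false calls was 4.62% for TNF against PBS, 2.17% for MoCe against PBS, 8.39% for MoCe_TNF against TNF, 6.67% for MoCe_TNF against MoCe and 3.19% for the interaction. For MoCe_TNF against TNF, 0 of 43 unchanged simulated lists were called by camera in a single simulation. Its genes were drawn independently, so it does not show how often camera calls unchanged lists of genes that vary together.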

Results

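Messenger RNA was sequenced from HaCaT cells, an established line of spontaneously immortalised human keratinocytes, the main cells of the epidermis. Cells were pretreated for 18 h with Mo90Ce10, a material known here only by a label that carries the symbols of molybdenum and cerium, or were left without it. They were then exposed for 6 h to TNF-α, a proinflammatory cytokine, or to the buffer PBS. This gave 4 groups of 3 libraries, called PBS, TNF, MoCe (material, then PBS) and MoCe_TNF (material, then TNF-α). By its title, the series asks whether Mo90Ce10 acts against inflammation by weakening the type I interferon response. The deposited table lists 20263 Ensembl genes with hg38 coordinates, and the 12 libraries held 38.3 to 47.9 M counts (M, 1e6) each. Mean totals were 41.0 M ± 2.40 (SD, n = 3) for PBS, 43.0 ± 1.84 for TNF, 41.8 ± 1.32 for MoCe and 45.7 ± 3.34 for MoCe_TNF. The labels do not say that the 3 libraries of a group came from separate cultures, so edgeR p-values measure only the spread between these libraries, which may be technical. Camera p-values with the preset correlation rest mainly on the spread across genes, and are not a measure of the spread between libraries. The first principal component held 30.3% of the variance and parted the pretreated libraries from the others. The second held 18.7% and parted the TNF-α libraries from the PBS libraries.

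The response of untreated keratinocytes to TNF-α (TNF against PBS) included rises of NF-kB, cytokine and interferon-stimulated genes. TNFAIP3, which encodes the ubiquitin-editing NF-kB inhibitor A20 (ENSG00000118503, chromosome 6, 137867188 to 137883312), rose from 77.4 ± 1.84 to 433 ± 8.20 CPM (counts per 1e6 counts, mean ± SD, n = 3). Its log2 fold change was 2.48 (SE 0.03, edgeR adjusted p = 4.4e-12). SOD2, the mitochondrial superoxide dismutase (chromosome 6, 159669057 to 159762529), rose from 185 ± 1.89 to 997 ± 18.0 CPM. CXCL8, a neutrophil chemokine (chromosome 4, 73740506 to 73743716), rose from 11.8 ± 0.950 to 77.1 ± 3.62 CPM, and CCL2, a monocyte chemokine (chromosome 17, 34255285 to 34257203), from 54.0 ± 0.934 to 298 ± 32.5 CPM. Of 28 NF-kB feedback and pathway genes tested, 21 rose and 1 fell, with the same counts when adjusted over the list alone (mean log2 fold change 0.82, camera adjusted p = 6.4e-41). The transcription factor subunits NFKB2 and RELB and the A20 partner TNIP1 rose by 1.44, 1.86 and 1.35 on the log2 scale. NFKBIA, the inhibitor of NF-kB, rose by 1.43 (SE 0.17).

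Inflammatory mediators rose together. Of 16 chemokine genes tested, 12 rose (15 adjusted over the list alone; mean 1.64, camera adjusted p = 2.5e-25), including CXCL16 (0.81) and the neutrophil chemokine CXCL1 (1.32). CCL20, a lymphocyte chemokine, rose by 2.03 (SE 0.22), and the interferon-inducible chemokines CXCL10 and CXCL11 by 4.28 (SE 0.47) and 2.74 (SE 0.57). Of 18 cytokine and growth factor genes, 10 rose and 1 fell (the same counts adjusted over the list alone; mean 1.10, adjusted p = 3.3e-15), among them IL1B (1.88), LIF (1.29), IL1A (1.904), IL32 (2.19) and IL6 (1.79, SE 0.13). The list of TNF receptors, ligands and adaptors had 9 higher and 1 lower of 20 (11 and 1 adjusted over the list alone; mean 0.84, adjusted p = 2.6e-10). Its members TNFRSF10B, TNFRSF9, TNFSF14 and TNFSF15 rose by 0.78, 2.76, 1.42 and 1.97. Of 27 psoriasis and IL-17 response genes, 18 rose and 3 fell (20 and 4 adjusted over the list alone; mean 1.14, adjusted p = 1.3e-23). They included the growth factor HBEGF (1.51), the complement component C3 (0.68) and SERPINB4 (1.16). Of 10 adhesion and surface genes, 7 rose (8 higher and 1 lower adjusted over the list alone; mean 0.64, adjusted p = 2.8e-12), and the adhesion receptor ICAM1 rose by 1.39 (SE 0.05). Complement and acute phase genes had 11 of 19 higher (11 adjusted over the list alone; mean 0.66, adjusted p = 4.0e-17).

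Interferon-responsive genes also rose with TNF-α. Of 58 type I interferon-stimulated genes tested, 52 rose and 0 fell (54 and 0 adjusted over the list alone; mean 0.77, camera adjusted p = 1.4e-72, 6.1e-07 with an estimated correlation). The antiviral GTPase MX1 (ENSG00000157601, chromosome 21, 41420515 to 41459214) rose from 68.4 ± 2.19 to 196 ± 2.36 CPM, and the oligoadenylate synthetases OAS1 and OAS3, neighbours on chromosome 12, rose by 1.12 (SE 0.04) and 1.01 (SE 0.03). IFIT3 and PARP14 rose by 1.23 and 0.96, IFIT1 by 1.05, ISG15 by 0.52, IFI44L by 1.28 and RSAD2 by 1.204. IFI27 had a log2 fold change of 0.11 (SE 0.23, edgeR adjusted p = 0.79). Of 25 interferon gamma response genes, 19 rose (21 adjusted over the list alone; mean 1.03, adjusted p = 4.1e-31), with GBP1, GBP4 and the peptide transporter TAP1 at 1.75, 1.76 and 0.92. Nucleic acid sensing genes had 11 of 19 higher (13 adjusted over the list alone; mean 0.67, adjusted p = 2.5e-14), among them IFIH1, IKBKE, DDX58 and TICAM1 at 1.11, 1.31, 0.92 and 0.72. Antigen presentation genes had 16 of 26 higher (18 adjusted over the list alone; mean 0.34, adjusted p = 3.3e-11). Of 22 interferon signalling components, 11 rose and 1 fell (12 and 1 adjusted over the list alone; mean 0.31, adjusted p = 7.5e-08). The transcription factors STAT2, IRF1 and IRF7 rose by 0.23, 0.82 and 0.89, and the receptor chains IFNGR1 and IFNAR1 by 0.72 and 0.26. IFNAR2 (0.22, SE 0.11, edgeR adjusted p = 0.21) and IRF9 (0.03, SE 0.37, adjusted p = 0.97) did not pass. Both overlap a gene on their strand, so their counts are uncertain here and in the other comparisons. No count of IFNB1, the gene of interferon beta, was found in any of the 12 libraries, and only 1 of 10 interferon ligand genes, IFNE, had enough counts to be tested.

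Other groups passed as well. Immediate early genes (15 of 33 higher, 17 adjusted over the list alone; mean 0.44, camera adjusted p = 7.3e-09) included the transcription factor JUN (1.04). EGFR ligand and feedback genes had 10 higher and 1 lower of 20 (13 and 2 adjusted over the list alone; mean 0.37, adjusted p = 1.1e-04). Genes of epithelial-mesenchymal transition and TGF-β had 8 higher and 2 lower of 25 (10 and 3 adjusted over the list alone; mean 0.19, adjusted p = 2.8e-05), among them INHBA (1.79), an activin subunit. Heat shock genes were higher (8 higher and 1 lower of 19, 8 and 2 adjusted over the list alone; mean 0.16, 0.08661 on the TPM scale and 0.2492 without PBS replicate 2, adjusted p = 0.0279), with adjusted p = 0.117 with an estimated correlation. Fatty acid genes were lower (9 of 21 lower, 10 adjusted over the list alone; mean -0.15, adjusted p = 0.00834), with adjusted p = 0.113 with an estimated correlation. Keratinocyte differentiation genes were lower as a list (8 lower and 3 higher of 30, 8 and 4 adjusted over the list alone; mean -0.13, adjusted p = 0.0365), with adjusted p = 0.297 with an estimated correlation. Without TNF replicate 1 or 3 the list's adjusted p was 0.0566 or 0.0609. TGM1, IVL and FLG, of the cornified envelope, fell by 0.66, 0.78 and 0.63, while the transcription factor PRDM1 rose by 1.71. Histone genes (6 of 17 lower, 6 adjusted over the list alone; mean -0.26, -0.4062 without TNF replicate 2, adjusted p = 0.0306) gave adjusted p = 0.0756 with an estimated correlation and 0.0546 without PBS replicate 1. Glucocorticoid targets (3 of 10 lower, 3 adjusted over the list alone; mean -0.42, -0.1874 on the TPM scale, adjusted p = 0.0427) gave adjusted p = 0.120 with an estimated correlation, 0.0537 without PBS replicate 1 and 0.0828 without TNF replicate 3.

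In all, 2800 of 14109 genes tested changed, 1608 higher and 1192 lower, of which 199 and 97 changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Beside those named, the 10 largest rises were of UBD, a ubiquitin-like modifier (3.51), TNF itself (3.31), KLHDC7B (2.86), the cytokine IL36G (2.85) and TMEFF1 (2.63, SE 0.59). The 10 largest falls were of RGS2 (-1.58), SEMA6D (-1.52), the elastase MMP12 (-1.39), the protease ADAMTS1 (-1.26), WNT11 (-1.24), DOCK8 (-1.24), PALMD (-1.24), the ephrin receptor EPHA4 (-1.21), VWA5B2 (-1.21) and PELI2 (-1.19). UBD and TMEFF1 share their strand with an overlapping gene (GABBR1 and a read-through transcript), so their counts are uncertain, and TMEFF1 had adjusted p = 0.0549 when the 2 groups were fitted alone.

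**Figure D1:**
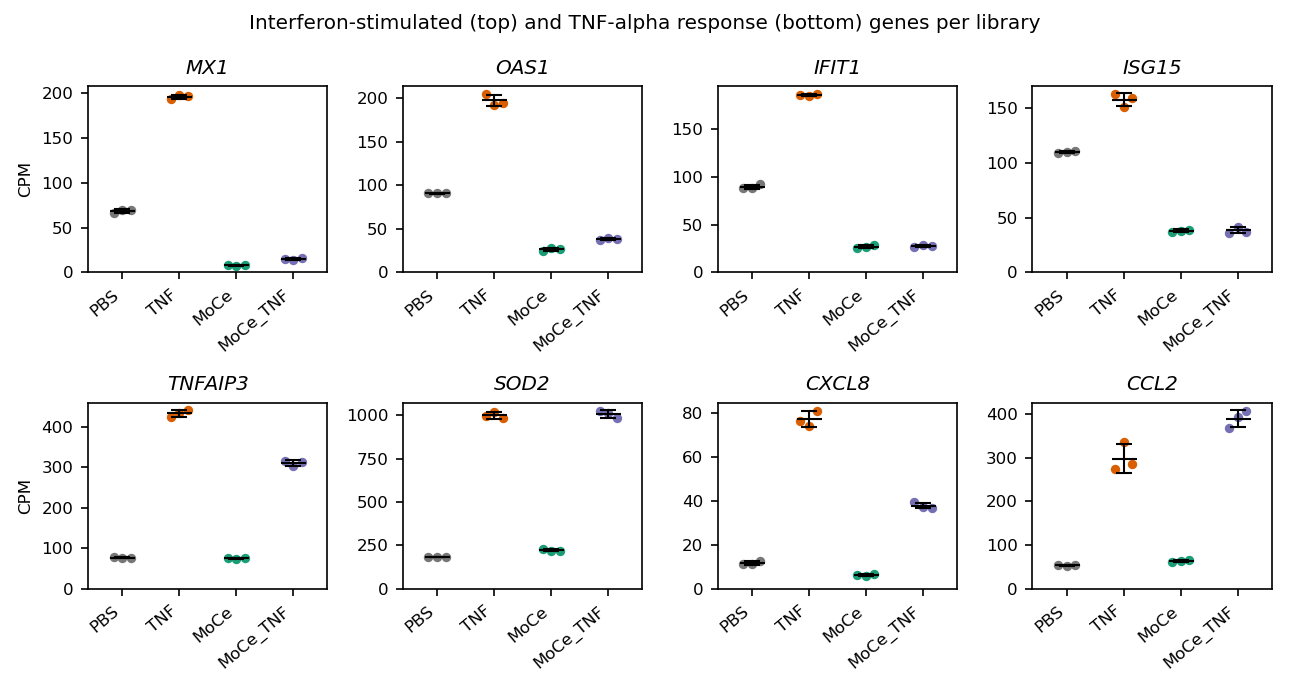
CPM (vertical axis, from 0) of 4 interferon-stimulated genes (top) and 4 TNF-α response genes (bottom) in each of the 12 libraries, by group; points are libraries, black marks the mean ± SD (n = 3). MX1 averaged 68.4, 196, 8.04 and 15.3 CPM in PBS, TNF, MoCe and MoCe_TNF, while SOD2 averaged 185, 997, 223 and 1006 CPM.

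With the material alone (MoCe against PBS), interferon-stimulated genes were below their level in untreated cells. No mock pretreatment is recorded here for the PBS and TNF groups. The material therefore cannot be told apart from the handling that came with it, here or in MoCe_TNF against TNF. Of 58 type I interferon-stimulated genes, 49 fell and 0 rose (51 and 0 adjusted over the list alone; mean log2 fold change -1.19, camera adjusted p = 3.1e-83). MX1 fell from 68.4 ± 2.19 to 8.04 ± 0.528 CPM (n = 3; log2 fold change -3.09, SE 0.06, edgeR adjusted p = 2.3e-10). OAS3 (chromosome 12, 112938352 to 112973249) fell by 1.94, OAS2 by 2.43 and OAS1 (chromosome 12, 112906777 to 112933222) by 1.78. IFIT1 fell by 1.73, ISG15 by 1.54, RSAD2 by 1.18, IFI27 by 3.10 and IFI44L by 4.33, the last from 5.37 ± 0.806 to 0.264 ± 0.0630 CPM. The transcription factor gene IRF7 fell by 1.01. STAT2 (-0.07, SE 0.03, edgeR adjusted p = 0.10), IRF9 (-0.68, SE 0.38, adjusted p = 0.20) and the receptor genes IFNAR1 (0.14, SE 0.05, adjusted p = 0.073) and IFNAR2 (-0.23, SE 0.11, adjusted p = 0.15) did not pass. IRF9 passed (adjusted p = 0.0430) without MoCe replicate 3, and IFNAR1 (adjusted p = 0.0496) without MoCe replicate 2. Interferon signalling components as a list did not pass (4 higher and 2 lower of 22, 4 and 2 adjusted over the list alone; mean -0.09, -0.1658 on the TPM scale, median 0.05, camera adjusted p = 0.37). Interferon gamma response genes had 15 lower and 2 higher of 25 (15 and 2 adjusted over the list alone; mean -0.54, adjusted p = 2.1e-06), with GBP1, NLRC5, TAP2 and WARS at -1.43, -1.13, -0.57 and -0.45. Antigen presentation genes had 17 lower and 2 higher of 26 (18 and 2 adjusted over the list alone; mean -0.43, adjusted p = 4.4e-07). In that list HLA-DRA fell by 1.22 and HLA-E rose by 0.46, both members of the HLA family, whose similar sequences make their counts uncertain. Nucleic acid sensing genes had 6 lower and 4 higher of 19 (7 and 4 adjusted over the list alone; mean -0.47, -0.307 on the TPM scale, adjusted p = 0.00329), including the RNA sensors DHX58 (-1.28), DDX58 (-1.08) and IFIH1 (-0.75).

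NF-kB genes did not pass against the other genes with the material alone (8 higher and 4 lower of 28, 8 and 4 adjusted over the list alone; mean 0.01, -0.0413 on the TPM scale, camera adjusted p = 0.33), while fry, which tests the list by itself, called them higher (adjusted p = 4.5e-04). TNFAIP3 (-0.04, SE 0.03, edgeR adjusted p = 0.37), NFKBIA (-0.18, SE 0.17, adjusted p = 0.46), IL1B (-0.17, SE 0.08, adjusted p = 0.14), CCL20 (-0.34, SE 0.23, adjusted p = 0.29), CXCL10 (-0.08, SE 0.55, adjusted p = 0.93) and CXCL11 (-1.23, SE 0.76, adjusted p = 0.25) did not pass. SOD2 rose by 0.27 (SE 0.03), ICAM1 by 0.48 (SE 0.05), IL6 by 0.47 (SE 0.13, adjusted p = 0.017) and IRF1 by 0.16 (SE 0.05, adjusted p = 0.029). The IL6 call was lost without PBS replicate 1 (adjusted p = 0.0606) or MoCe replicate 3 (0.0576). That of IRF1 was lost without PBS replicates 1 and 3 (0.106 and 0.0750) and MoCe replicates 1, 2 and 3 (0.0839, 0.0676 and 0.0575), each left out singly. With only these 2 groups fitted, adjusted p was 0.0524 for IL6 and 0.0525 for IRF1. CXCL8 fell by 0.90 and CXCL1 by 0.99. Chemokines as a list were lower (4 lower and 2 higher of 16, 5 and 2 adjusted over the list alone; mean -0.52, adjusted p = 0.0230), with adjusted p = 0.0674 with an estimated correlation. Psoriasis and IL-17 response genes had 13 lower and 4 higher of 27 (13 and 5 adjusted over the list alone; mean -0.37, -0.1787 without PBS replicate 1, adjusted p = 4.1e-07). The protease inhibitors SERPINB3 and SERPINB4, near-identical neighbours whose counts are uncertain, fell by 1.99 and 1.91, the calcium-binding protein gene S100A9 by 1.79 and the keratin gene KRT6A by 0.59.

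Metabolic and stress genes changed as well. Hypoxia and glycolysis genes rose (19 higher and 4 lower of 32, 20 and 4 adjusted over the list alone; mean 0.41, camera adjusted p = 3.7e-09). The aldolase gene ALDOC rose from 145 ± 0.628 to 305 ± 2.37 CPM, and NDRG1, P4HA1 and ADM rose by 0.70, 0.78 and 0.67. Cholesterol synthesis genes rose (19 higher and 0 lower of 26, 19 and 0 adjusted over the list alone; mean 0.37, adjusted p = 1.9e-11), among them IDI1, MVD, MSMO1 and ACAT2, by 0.67, 0.70, 0.85 and 0.55. Targets of NRF2, the regulator of antioxidant genes, fell (17 lower and 3 higher of 31, 17 and 3 adjusted over the list alone; mean -0.36, adjusted p = 1.1e-07). The quinone reductase NQO1 fell from 183 ± 3.58 to 127 ± 0.819 CPM, the transporter ABCC3 fell by 0.53, and the close paralogs AKR1C1 and AKR1C3 by 0.88 and 0.89. Endoplasmic reticulum stress genes fell (9 lower and 2 higher of 18, 9 and 2 adjusted over the list alone; mean -0.24, adjusted p = 3.0e-04), among them the chaperone HSPA5 (chromosome 9, 125234853 to 125241330), from 416 ± 1.08 to 238 ± 2.16 CPM. Heat shock genes fell (9 lower and 1 higher of 19, 9 and 2 adjusted over the list alone; mean -0.21, -0.1275 without PBS replicate 2 and -0.3221 without MoCe replicate 1, adjusted p = 3.2e-04), HSPA8 and HSPH1 by 0.68 and 0.40. Proliferation genes fell (22 lower and 3 higher of 42, 24 and 4 adjusted over the list alone; mean -0.33, adjusted p = 1.9e-12). The mitotic kinesin KIF20A (chromosome 5, 138178719 to 138187715) fell from 156 ± 1.27 to 70.3 ± 2.42 CPM, and CCND1, TPX2 and CDC20 by 0.75, 0.74 and 0.82. Ribosomal protein genes were higher (37 of 42, 39 adjusted over the list alone; mean 0.30, adjusted p = 1.3e-12), with adjusted p = 0.0581 with an estimated correlation. Immediate early genes were higher (11 higher and 3 lower of 33, 12 and 3 adjusted over the list alone; mean 0.25, 0.1531 on the TPM scale, adjusted p = 0.0178), with adjusted p = 0.164 with an estimated correlation. Among them CYR61 rose by 1.31 and EGR1 fell by 0.81. Genes of epithelial-mesenchymal transition were higher as a list (10 higher and 2 lower of 25, 10 and 4 adjusted over the list alone; mean 0.22, 0.1012 on the TPM scale, adjusted p = 0.0145), among them the transcription factor SNAI2 (1.00).

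Together 4618 genes changed with the material alone, 2391 higher and 2227 lower, with 203 and 192 of them at least 2-fold (edgeR). Scaled by TPM and tested with limma, 32.1% of 4210 changed genes were higher, against 51.8% here. The 10 largest rises were of IGHE, an immunoglobulin gene (2.42), CDH5, a cadherin of endothelial cells (2.34), CLCA4 (2.28), the growth factor FGF1 (2.25), the mucin MUC4 (2.20), TP53INP2 (2.01), SV2A (1.89), CLMN (1.89), SYT14 (1.86, SE 0.40) and GPRC5B (1.73). CDH5 (chromosome 16, 66366622 to 66404786) rose from 3.74 ± 0.220 to 18.9 ± 3.48 CPM. Beside IFI44L, IFI27 and MX1, the largest falls were of the interferon-stimulated genes MX2 (-4.41), BST2 (-3.08) and IFI6 (-2.93), and of IGFN1 (-3.55), the keratin gene KRT1 (-3.07), SAMD11 (-3.04) and ID4 (-2.99), an inhibitor of DNA binding.

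With TNF-α present (MoCe_TNF against TNF), the comparison the title of the series is about, pretreated cells held less of nearly every interferon-stimulated transcript. Of 58 type I interferon-stimulated genes, 56 fell and 0 rose (57 and 0 adjusted over the list alone; mean log2 fold change -1.66, median -1.34, camera adjusted p = 9.2e-144, 3.8e-08 with an estimated correlation). MX1 was 15.3 ± 0.982 CPM against 196 ± 2.36 CPM (n = 3; log2 fold change -3.67, SE 0.06, edgeR adjusted p = 5.9e-11), below the 68.4 ± 2.19 CPM of untreated cells. IFIT1 (chromosome 10, 89392546 to 89406486) was 27.7 ± 1.19 against 186 ± 1.37 CPM, OAS1 38.1 ± 1.07 against 197 ± 6.76 CPM and ISG15 (chromosome 1, 1001138 to 1014541) 38.5 ± 2.75 against 158 ± 6.14 CPM. Further falls were those of OAS3 (-2.18), OAS2 (-2.835), RSAD2 (-2.221), IFI27 (-3.46) and IFI44L (-5.086). IRF7 fell by 1.56 and STAT2 by 0.33 (SE 0.03). IRF1 (-0.09, SE 0.05, edgeR adjusted p = 0.16), IFNAR2 (0.15, SE 0.11, adjusted p = 0.34) and IRF9 (-0.63, SE 0.38, adjusted p = 0.22) did not pass, and IRF9 passed (adjusted p = 0.00903) without MoCe_TNF replicate 1. IFNAR1 rose by 0.20 (SE 0.05, adjusted p = 0.014), a call lost without TNF replicate 2 (0.0504). The chemokines CXCL10 and CXCL11 fell by 2.45 (SE 0.40) and 1.99 (SE 0.53). IFIT1, IRF1, CXCL10, CXCL11, WARS and TAP1 overlap genes on the opposite strand, and the counting is not stated to use strand. Interferon gamma response genes had 18 lower and 1 higher of 25 (19 and 1 adjusted over the list alone; mean -0.84, adjusted p = 6.6e-13), with GBP1, NLRC5, WARS and TAP1 at -1.82, -1.45, -0.78 and -0.52. Antigen presentation genes had 20 lower and 1 higher of 26 (20 and 1 adjusted over the list alone; mean -0.56, adjusted p = 2.9e-10), and nucleic acid sensing genes 8 lower and 1 higher of 19 (10 and 2 adjusted over the list alone; mean -0.48, adjusted p = 1.0e-04). CD74, the invariant chain, fell by 1.48 and DHX58 by 1.64. Interferon signalling components as a list did not pass (5 higher and 4 lower of 22, 6 and 4 adjusted over the list alone; mean -0.15, median 0.09, adjusted p = 0.17).

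TNF-α response genes divided in this comparison. TNFAIP3 was 310 ± 7.44 against 433 ± 8.20 CPM (-0.48, SE 0.03), CXCL8 fell by 1.02 (SE 0.07), CXCL1 by 0.73 and IL1B by 0.47 (SE 0.08). SOD2 was 1006 ± 23.3 against 997 ± 18.0 CPM (0.01, SE 0.03, edgeR adjusted p = 0.76). NFKBIA (-0.10, SE 0.16, adjusted p = 0.66) and CCL20 (-0.49, SE 0.20, adjusted p = 0.083) did not pass. ICAM1 rose by 0.53 (SE 0.04), IL6 by 0.49 (SE 0.12, adjusted p = 0.0085), CCL2 by 0.39 (SE 0.07) and TNFRSF9 by 1.83 (SE 0.15). Neither the NF-kB list (7 higher and 5 lower of 28, 7 and 5 adjusted over the list alone; mean -0.09, median 0.01, camera adjusted p = 0.81) nor the cytokine list (5 higher and 4 lower of 18, 5 and 4 adjusted over the list alone; mean 0.13, on the TPM scale -0.0997, adjusted p = 0.83, test direction lower) passed. Chemokines as a list were lower (8 lower and 3 higher of 16, 9 and 3 adjusted over the list alone; mean -0.75, adjusted p = 0.0131), with adjusted p = 0.0540 with an estimated correlation. Psoriasis and IL-17 response genes fell (16 lower and 2 higher of 27, 20 and 4 adjusted over the list alone; mean -0.69, adjusted p = 4.3e-10), among them SERPINB4 (-2.15), SERPINB3 (-1.997), S100A9 (-2.45) and KRT6A (-0.55).

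The other groups that passed had the direction seen without TNF-α. NRF2 targets had 17 lower and 4 higher of 31 (19 and 4 adjusted over the list alone; mean -0.37, camera adjusted p = 2.5e-07), endoplasmic reticulum stress genes 9 lower and 2 higher of 18 (10 and 2 adjusted over the list alone; mean -0.28, adjusted p = 3.7e-05) and heat shock genes 11 lower and 1 higher of 19 (12 and 1 adjusted over the list alone; mean -0.30, adjusted p = 2.5e-05). HSPA5, HSPA8 and NQO1 fell by 1.02, 0.87 and 0.62. Proliferation genes had 23 lower and 10 higher of 42 (24 and 11 adjusted over the list alone; mean -0.29, adjusted p = 4.1e-08), and KIF20A and CCND1 fell by 1.16 and 0.82. Cholesterol genes had 20 higher and 1 lower of 26 (20 and 2 adjusted over the list alone; mean 0.37, adjusted p = 2.9e-10), and hypoxia and glycolysis genes 15 higher and 4 lower of 32 (16 and 4 adjusted over the list alone; mean 0.29, 0.1456 on the TPM scale, adjusted p = 1.0e-04). MSMO1 and ALDOC rose by 0.90 and 1.08. Ribosomal protein genes were higher (36 of 42, 37 adjusted over the list alone; mean 0.31, adjusted p = 3.7e-12), with adjusted p = 0.0727 with an estimated correlation. Here 5157 genes changed, 2576 higher and 2581 lower, and 238 and 271 at least 2-fold (edgeR). Scaled by TPM and tested with limma, 34.0% of 4544 changed genes were higher, against 49.95% here. The largest rises, beside TNFRSF9, were of FGF1 (2.58), CLCA4 (2.56), SYT14 (2.52, SE 0.41), CDH5 (2.12), TP53INP2 (2.05), PKD1L2 (1.997), MUC4 (1.95) and SV2A (1.83). The largest falls, beside IFI44L, MX1 and IFI27, were of IGFN1 (-5.48), MX2 (-4.48), the nucleotide kinase CMPK2 (-3.54), IFI6 (-3.43), XAF1 (-3.32) and BST2 (-3.32). TOMM6 (6.17, SE 1.94, edgeR adjusted p = 0.029) and UGT1A8 (-6.00, SE 1.28, adjusted p = 0.0038) also met the rule, but both overlap genes on their strand and their libraries split within a group. TOMM6 held 40.3, 0.487 and 42.4 CPM in the MoCe_TNF libraries, and without TNF replicates 1, 2 and 3 and MoCe_TNF replicates 1 and 3 its adjusted p was 0.0871, 0.0797, 0.0830, 0.0570 and 0.0590. UGT1A8 held 51.6, 36.3 and 0.690 CPM in the TNF libraries.

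Set against the TNF-α response itself, 645 of the 1608 genes raised by TNF-α were lower in MoCe_TNF than in TNF and 332 were higher. Independent lists would share 294.2 genes in the first direction. No such number was computed for genes that moved the same way in both comparisons. A general tendency of genes to be called in both is therefore not separated from reversal. Of the 1192 genes lowered by TNF-α, 516 were higher with the material and 184 lower, where independent lists would share 217.6. Both comparisons contain the TNF libraries, which tie them together: in 20 simulations with no effect the covariance of the log2 fold changes was -0.0265 against -0.0746 observed. The correlation across genes was -0.307 observed and -0.499 simulated. The 3 TNF libraries were too few to split, so part of the excess may come from the libraries shared.

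After pretreatment TNF-α still raised NF-kB, chemokine and cytokine genes (MoCe_TNF against MoCe). Of 28 NF-kB genes, 20 rose and 1 fell (23 and 1 adjusted over the list alone; mean log2 fold change 0.71, camera adjusted p = 2.8e-42). TNFAIP3 rose from 75.3 ± 0.641 to 310 ± 7.44 CPM (n = 3; 2.04, SE 0.03, edgeR adjusted p = 3.0e-11) and SOD2 from 223 ± 5.32 to 1006 ± 23.3 CPM. NFKB2, RELB and TNIP1 rose by 1.23, 1.48 and 1.08, and NFKBIA by 1.51 (SE 0.17). Of 16 chemokines, 10 rose (14 adjusted over the list alone; mean 1.40, adjusted p = 4.0e-29). CCL2 rose from 63.9 ± 2.02 to 389 ± 19.1 CPM, CXCL8 from 6.33 ± 0.461 to 37.9 ± 1.33 CPM, and CXCL1, CXCL16 and CCL20 by 1.58, 0.82 and 1.88. CXCL10 rose by 1.91 (SE 0.48, adjusted p = 0.022), a call lost without MoCe replicate 2 (0.0655) and MoCe_TNF replicates 1 and 2 (0.0546 and 0.0603), and with only these groups fitted (0.0675). CXCL11 did not pass (1.99, SE 0.71, adjusted p = 0.088) but did with the DESeq2 Wald test (adjusted p = 0.0274). Of 18 cytokine genes, 10 rose (11 higher and 1 lower adjusted over the list alone; mean 0.93, adjusted p = 2.3e-14), IL1B by 1.57, LIF by 1.04, IL6 by 1.80 and IL32 by 1.84. ICAM1 rose by 1.43 (SE 0.05), and adhesion genes had 8 higher and 1 lower of 10 (8 and 1 adjusted over the list alone; mean 0.56, adjusted p = 8.0e-11). TNF receptor and ligand genes (8 higher and 1 lower of 20, 10 and 2 adjusted over the list alone; mean 0.76, adjusted p = 2.9e-09), psoriasis genes (17 higher and 4 lower of 27, 19 and 4 adjusted over the list alone; mean 0.82, adjusted p = 1.2e-19) and complement genes (11 of 19 higher, 12 higher and 1 lower adjusted over the list alone; mean 0.62, adjusted p = 1.8e-17) also rose.

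The interferon-stimulated genes rose less after pretreatment and by fewer calls. Of 58, 26 rose and 0 fell (28 and 2 adjusted over the list alone; mean 0.29, camera adjusted p = 2.6e-11). MX1 rose from 8.04 ± 0.528 to 15.3 ± 0.982 CPM (0.93, SE 0.06), OAS1 by 0.53, OAS3 by 0.77, PARP14 by 0.58 and OAS2 by 0.66. IFIT1 (0.03, SE 0.05, edgeR adjusted p = 0.71), ISG15 (0.02, SE 0.05, adjusted p = 0.84), IFI27 (-0.24, SE 0.28, adjusted p = 0.61), IFI44L (0.53, SE 0.32, adjusted p = 0.32) and RSAD2 (0.16, SE 0.09, adjusted p = 0.26) did not pass, though RSAD2 passed (0.0426) without MoCe_TNF replicate 3. IRF7 rose by 0.34 (SE 0.06), IRF1 by 0.57, IFNAR1 by 0.32 and IFNAR2 by 0.59. STAT2 (-0.02, SE 0.03, adjusted p = 0.70) and IRF9 (0.08, SE 0.38, adjusted p = 0.92) did not pass. Interferon gamma response genes had 15 of 25 higher (18 adjusted over the list alone; mean 0.72, 0.4475 on the TPM scale, adjusted p = 1.5e-19), GBP1, TAP1 and GBP4 at 1.36, 0.73 and 1.19. Nucleic acid sensing genes had 9 of 19 higher (11 adjusted over the list alone; mean 0.66, 0.3779 on the TPM scale, adjusted p = 5.3e-12), antigen presentation genes 12 of 26 (13 adjusted over the list alone; mean 0.21, adjusted p = 9.4e-07) and interferon signalling components 10 higher and 1 lower of 22 (11 and 1 adjusted over the list alone; mean 0.26, adjusted p = 1.5e-06). Immediate early genes (13 higher and 1 lower of 33, 16 and 1 adjusted over the list alone; mean 0.27, adjusted p = 1.5e-07), EGFR genes (5 higher and 2 lower of 20, 6 and 2 adjusted over the list alone; mean 0.24, adjusted p = 0.00557) and genes of epithelial-mesenchymal transition (7 higher and 3 lower of 25, 7 and 3 adjusted over the list alone; mean 0.19, adjusted p = 3.5e-04) were higher.

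Lists that lost their call with an estimated correlation were the fatty acid genes (9 lower and 1 higher of 21, 10 and 1 adjusted over the list alone; mean -0.14, adjusted p = 0.0946 with an estimated correlation), junction genes and histone genes. Junction and barrier genes were higher (6 higher and 2 lower of 25, 7 and 3 adjusted over the list alone; mean 0.13, 0.005224 on the TPM scale and 0.2935 without MoCe replicate 3, camera adjusted p = 0.0225), with adjusted p = 0.0529 with an estimated correlation and 0.0676 without MoCe_TNF replicate 1. The gap junction gene GJB2 rose by 1.56 and GJA1 fell by 0.88. Histone genes (2 of 17 lower, 2 adjusted over the list alone; mean -0.25, -0.1621 without MoCe_TNF replicate 2, adjusted p = 0.0394) gave adjusted p = 0.0829 with an estimated correlation, 0.109 without MoCe replicate 3 and 0.0760 without MoCe_TNF replicate 2. In this comparison 2145 genes changed, 1253 higher and 892 lower, and 137 and 56 at least 2-fold (edgeR). The largest rises included UBD (3.05), TNF (2.83), TNFRSF9 (2.49), PGLYRP4 (2.37), VNN1 (2.11) and the integrin gene ITGAM (2.06). The largest falls were of PRRG1 (-1.53, SE 0.38), IGHE (-1.52), RGS2 (-1.31), SLC47A2 (-1.29), EPHA4 (-1.16), GINS4 (-1.10, SE 0.27), PKD1L2 (-1.07), PLA2G10 (-1.04), RAB26 (-1.03) and NRG2 (-0.998). PRRG1, which overlaps a gene on its strand, lost its call without MoCe replicates 2 and 3 (edgeR adjusted p = 0.0548 and 0.0557) and MoCe_TNF replicates 1 and 2 (0.0745 and 0.0579). GINS4 lost it without MoCe_TNF replicates 1 and 3 (0.0567 and 0.0670) and with only these groups fitted (0.0787).

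**Figure D2:**
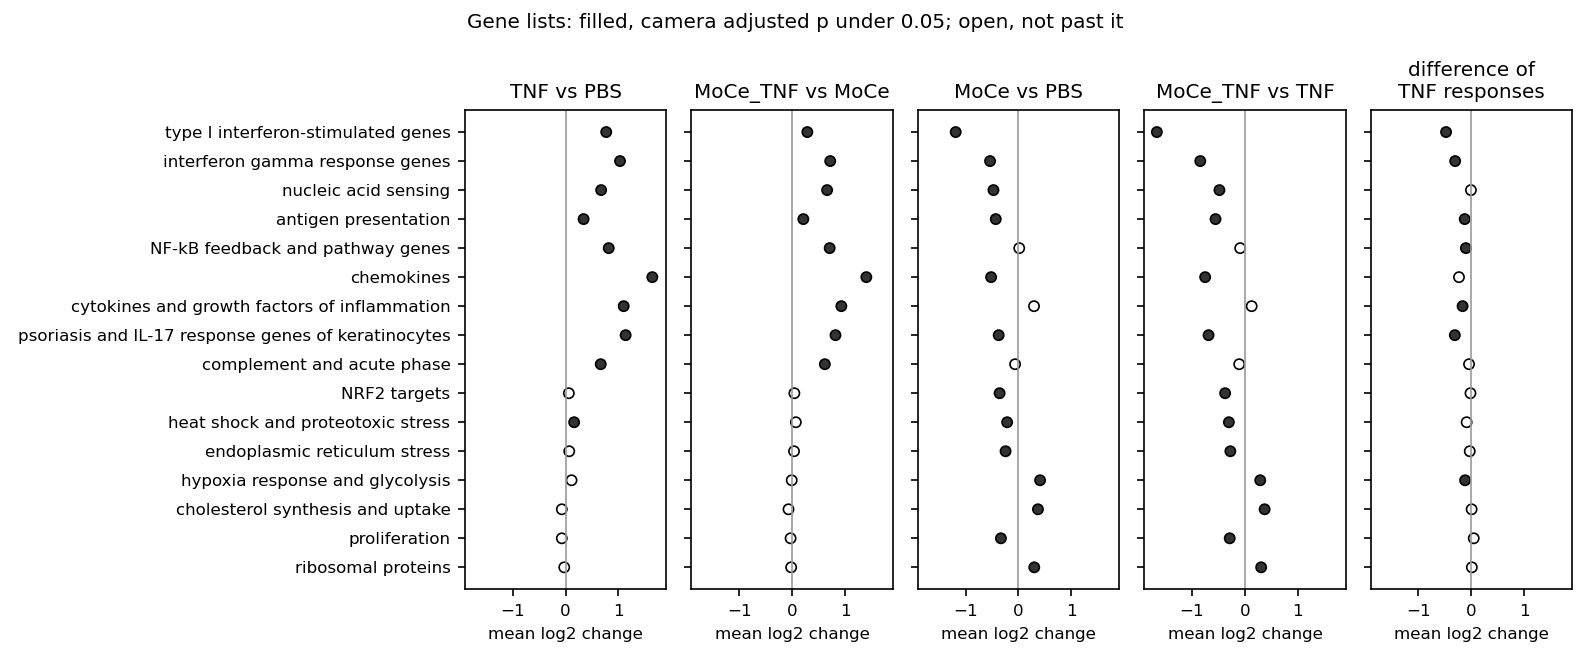
Mean log2 fold change (horizontal axis) of 16 gene lists in the 4 comparisons and in the difference of the TNF-α responses; filled circles passed camera at adjusted p under 0.05, open circles did not. The type I interferon list lies at 0.77 and 0.29 for TNF-α without and with pretreatment and at -1.19 and -1.66 for the material without and with TNF-α.

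The TNF-α responses with and without pretreatment were then compared directly, as the interaction of the 2 treatments. The response of the type I interferon-stimulated genes was lower by 0.48 on the log2 scale (mean -0.48, median -0.45, camera adjusted p = 2.2e-94, n = 3 libraries per group), and 23 of its 58 members passed with a smaller response and 0 with a larger one (44 and 0 adjusted over the list alone). IFIT1 differed by -1.02 (SE 0.06, edgeR adjusted p = 8.0e-05), the related IFIT3 by -0.90 (SE 0.05), RSAD2 by -1.04, CMPK2 by -1.11, the deubiquitinase USP18 by -1.01, IFI44 by -0.80, MX1 by -0.59 and OAS1 by -0.59. Among TNF-α response genes TNFAIP3 differed by -0.44 (SE 0.04, adjusted p = 0.0021). CYP24A1, the vitamin D hydroxylase (chromosome 20, 54153449 to 54173973), rose from 24.1 ± 1.76 to 65.2 ± 1.83 CPM without and from 20.6 ± 0.644 to 29.7 ± 1.72 CPM with pretreatment, a difference of -0.91. IGFBP3 (chromosome 7, 45912245 to 45921874), which binds insulin-like growth factors, went from 89.7 ± 15.9 to 110 ± 1.86 CPM without and from 96.5 ± 4.43 to 280 ± 8.16 CPM with pretreatment (1.249, SE 0.14, adjusted p = 0.0034). SCEL, a gene of the cornified envelope, differed by 0.54 and IGFN1 by -1.94 (SE 0.26).

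Of the other named genes, those that passed on all 12 libraries lost their call on omission of single libraries. STAT2 (-0.25, SE 0.04, edgeR adjusted p = 0.045) passed only without MoCe_TNF replicate 1, and without each other library its adjusted p was 0.0762 to 0.152. With DESeq2 size factors it was 0.0614 and with no filter on low counts 0.0699. ADI1 (1.40, SE 0.22) passed only without MoCe_TNF replicate 3 (otherwise 0.0553 to 0.0887). GBP4 (-0.58, SE 0.10) passed only without PBS replicate 1 and MoCe replicate 2 (otherwise 0.0773 to 0.155; 0.0587 with no filter) and HPGD (0.51, SE 0.09) only without PBS replicate 2 and MoCe replicate 2 (otherwise 0.0532 to 0.125). SOD2 (-0.26, SE 0.04) passed only without MoCe replicate 3 and MoCe_TNF replicate 1 (otherwise 0.0541 to 0.0909), IL1A (-1.001, SE 0.16) only without PBS replicate 2 and MoCe replicate 3 (otherwise 0.0536 to 0.0854), and CD74 (-0.81, SE 0.13) only without PBS replicate 3, TNF replicate 1 and MoCe replicate 3 (otherwise 0.0656 to 0.0980). WARS (-0.34, SE 0.06) passed only without MoCe replicate 3 and MoCe_TNF replicates 1 and 3 (otherwise 0.0541 to 0.113). IRF7 (-0.55, SE 0.08) lost its call without PBS replicates 1 and 3, TNF replicate 3, MoCe replicates 1 and 2 and MoCe_TNF replicates 1 and 2 (0.0532 to 0.0680), and ISG15 (-0.50, SE 0.07) without PBS replicates 1 and 2, TNF replicates 1 and 3, MoCe replicate 2 and MoCe_TNF replicate 3 (0.0504 to 0.0598). CRYZ (0.85, SE 0.12) lost it without PBS replicate 1 (0.0538) and MoCe_TNF replicate 2 (0.0504). The differences of NFKBIA (0.07, SE 0.23), CXCL8 (-0.12, SE 0.10), CCL20 (-0.14, SE 0.31), IL6 (0.01, SE 0.18), IL1B (-0.31, SE 0.11), ICAM1 (0.05, SE 0.06), CXCL10 (-2.36, SE 0.69), CXCL11 (-0.75, SE 0.99), IFNAR1 (0.06, SE 0.08), IFNAR2 (0.37, SE 0.16), IRF1 (-0.25, SE 0.07), IRF9 (0.05, SE 0.53), IFI27 (-0.36, SE 0.36) and IFI44L (-0.75, SE 0.38) did not pass, with edgeR adjusted p from 0.283 (IRF1) to 0.995 (IL6), though CXCL10 passed with the DESeq2 Wald test (adjusted p = 0.0112).

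Among lists, the interferon gamma response genes also had a smaller response (mean -0.31, camera adjusted p = 2.3e-08; 2 of 25 lower, 9 adjusted over the list alone). These 2 interferon lists passed with an estimated correlation too (2.1e-07 and 0.00303), while 9 lists lost their call. With adjusted p = 0.0628 with an estimated correlation these were antigen presentation (mean -0.13), NF-kB genes (mean -0.10; 1 of 28 lower, 4 adjusted over the list alone), hypoxia and glycolysis (-0.12), aryl hydrocarbon receptor targets (-0.29), vitamin D and retinoid targets (-0.12), cytokines (-0.17) and psoriasis genes (-0.31). TNF receptors (-0.08) and junction genes had adjusted p = 0.0899 with an estimated correlation. Junction genes were called higher, with a mean of -0.00018 and a median of 0.04, so mean and test differ in sign. On the TPM scale the means were -0.1985 for psoriasis genes, -0.1403 for aryl hydrocarbon receptor targets and -0.04184 for junction genes. The psoriasis mean was -0.5087 without PBS replicate 1 and -0.1473 without MoCe replicate 2. The vitamin D mean was -0.03033 without TNF replicate 3, -0.03296 without MoCe replicate 2, -0.04205 without MoCe_TNF replicate 1 and -0.3914 without MoCe_TNF replicate 3. The cytokine mean was -0.4051 without PBS replicate 1, and -0.2522 to -0.2611 without TNF replicate 1 or 3, MoCe replicate 3 or MoCe_TNF replicate 3. The mean of TNF receptors was -0.1402 without PBS replicate 1, -0.04953 without PBS replicate 3, -0.05406 without TNF replicate 3 and -0.03681 without MoCe replicate 1. That of hypoxia genes was -0.0762 without TNF replicate 1. The junction mean, near 0, changed in size or sign without any of the 12 libraries (-0.02914 without TNF replicate 2 to 0.1646 without MoCe replicate 3). In these 8 lists other than NF-kB, 3 members passed in all, CD74, CYP24A1 and IL1A, and adjusted over the list alone 8 passed. Without a library, calls were lost by cytokines and psoriasis genes (MoCe replicate 2, adjusted p = 0.0681 and 0.0762; MoCe_TNF replicate 1, 0.0545 for both) and vitamin D targets (MoCe_TNF replicate 1, 0.0545). TNF receptors lost theirs without PBS replicate 3, TNF replicate 3, MoCe replicates 1 and 2 and MoCe_TNF replicates 1 and 3 (0.0681 to 0.0956). Junction genes lost theirs without PBS replicates 1 and 2, TNF replicates 2 and 3, MoCe replicates 1 and 2 and MoCe_TNF replicate 1 (0.0693 to 0.115).

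For single genes the interaction was called 55 times, 8 with a larger and 47 with a smaller or more negative response after pretreatment, while 1053 genes had an unadjusted p under 0.05 (edgeR). The count was 34 without PBS replicate 1, 35 without TNF replicate 1, 33 without TNF replicate 3, 33 without MoCe replicate 1 and 36 without MoCe_TNF replicate 2. Across all 14109 genes the 2 responses, which share no library, correlated at Pearson r = 0.478 and Spearman rho = 0.579, with a slope of 0.448 for the response after pretreatment on that without it. Genes are not independent replicates, so no p-value is attached, and the slope was 0.116 and r 0.122 when no filter on low counts was applied, and 0.711 and 0.810 over called genes only. Noise in the log2 fold changes lowers a slope over all genes, so 0.448 is not the share of the response kept. Of the called genes, 1027 were higher and 585 lower in both responses and 2 went in opposite directions, where independent lists would share 142.8 and 75.4. The effects of the material with and without TNF-α correlated at r = 0.636 (rho = 0.719), and at r = 0.210 without the filter. They shared 1896 higher and 1805 lower genes, with 7 in opposite directions, where independent lists would share 436.6 and 407.4.

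**Figure D3:**
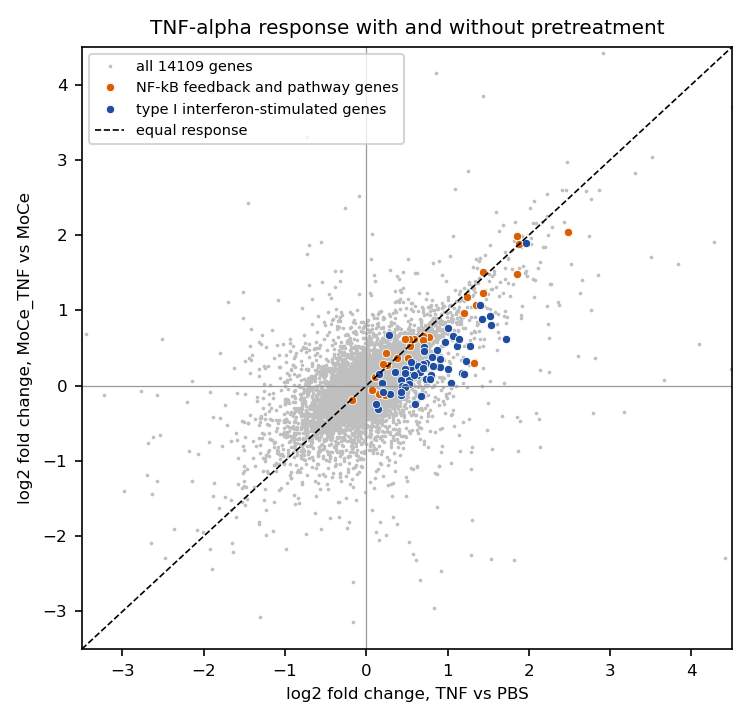
Log2 fold change by TNF-α without pretreatment (horizontal axis) and after it (vertical axis) for the 14109 genes tested, of which 25 lie outside the drawn range; the dashed line marks equal responses. Type I interferon-stimulated genes (blue) average 0.77 without and 0.29 with pretreatment, and NF-kB genes (orange) 0.82 and 0.71.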

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

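The tests of explanations in the last 3 paragraphs, and fry and the estimated correlation for single lists other than the type I interferon-stimulated genes, were chosen only after the result was seen. The responses to TNF-α with and without pretreatment were compared by the interaction test, and the genes and lists of this and the next paragraph are those whose response differed. In edgeR 55 genes were called. Of 100 splits of the 12 libraries into 4 groups of 3, the real one included, 2 called as many (highest other 529). Each split puts 6 libraries on either sign of the contrast. The split that called 529 genes placed 5 of 6 pretreated libraries on 1 side and 4 of 6 TNF-α libraries on 1 side. Of 5 splits of that makeup it alone called more than 2 genes, so the makeup by itself does not account for its count. The cause was not tested. Splits that mix the treatments within a group widen its spread, so their low counts do not show that 55 is more than chance would give. For the comparisons of 3 against 3 libraries, 10 splits cannot give a share under 0.05. Of these 10, 1 split, the real one, called as many genes in each: 2800 for TNF against PBS (highest other 2), 4618 for MoCe against PBS (highest other 2), 5157 for MoCe_TNF against TNF (highest other 1) and 2145 for MoCe_TNF against MoCe (highest other 3).

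List means that differed between the responses (camera, log2 scale) were -0.48 for type I interferon-stimulated genes, -0.31 for interferon gamma response genes, -0.13 for antigen presentation, -0.10 for NF-kB genes, -0.0825 for TNF receptors, -0.17 for cytokines, -0.31 for psoriasis genes, -0.12 for hypoxia and glycolysis, -0.00018 for junctions and barrier genes (test direction higher), -0.29 for aryl hydrocarbon receptor targets and -0.12 for vitamin D and retinoid targets. On the TPM scale the means were -0.1985 for psoriasis genes, -0.1403 for aryl hydrocarbon receptor targets and -0.04184 for junctions. The psoriasis mean was -0.1473 without MoCe replicate 2 and -0.5087 without PBS replicate 1, and the vitamin D mean -0.03033 without TNF replicate 3 and -0.3914 without MoCe_TNF replicate 3. With an estimated correlation the first 2 passed (adjusted p = 2.1e-07 and 0.00303), and the others had adjusted p = 0.0628 or 0.0899. Genes named in the report whose responses differed had a larger response for ADI1 (1.40), IGFBP3 (1.249), CRYZ (0.85), SCEL (0.54) and HPGD (0.51). The difference was negative for IGFN1 (-1.94), CMPK2 (-1.11), RSAD2 (-1.04), IFIT1 (-1.02), USP18 (-1.01), IL1A (-1.001), CYP24A1 (-0.91), IFIT3 (-0.90), CD74 (-0.81), IFI44 (-0.80), MX1 (-0.59), OAS1 (-0.59), GBP4 (-0.58), IRF7 (-0.55), ISG15 (-0.50), TNFAIP3 (-0.44), WARS (-0.34), SOD2 (-0.26) and STAT2 (-0.25).

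Type I interferon-stimulated genes were lower after pretreatment with and without TNF-α. Scaling between libraries would move genes of equal expression alike, but the list mean less that of expression-matched genes was -1.181 (SE 0.024) without TNF-α and -1.653 (SE 0.0125) with it. A single library cannot account for it, since the per-library list means of pretreated and other libraries were apart by 1.125 without and 1.624 with TNF-α. A candidate explanation is an effect of the pretreatment on these genes, found and tested on the same data. Whether fewer interferon ligands, a weaker signal or another step lies behind it was not tested.

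The TNF-α response of type I interferon-stimulated genes was smaller after pretreatment. Low counts would spare abundant members, but the 31 members with a mean of at least 50 CPM over all 12 libraries had a mean difference of -0.4259 (SE 0.031). That mean includes the libraries without pretreatment. Members with far fewer counts after it, such as MX1, are among the 31, so low counts after pretreatment are not fully excluded. Leaving out each library gave at the weakest -0.459. Other genes raised by TNF-α (1526, without the members of the 3 interferon lists) kept 0.755 of their response after pretreatment. This share is a slope through the origin over genes picked by their call in TNF against PBS. As a ratio of mean responses, an unlike measure, the type I interferon list kept 0.377 and the NF-kB genes 0.872. With the share of the 1526 genes removed, a difference of -0.2936 (SE 0.023) was left for the type I interferon list. A weaker response of this list may be a biological effect of the pretreatment, which stays a hypothesis, and since interferon gamma response genes were weaker too and not set against it, it is not shown to be confined to this list.

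Ribosomal protein genes were higher after pretreatment. Genes matched to them in transcript length and expression rose by only 0.01965 (SE 0.0058) with TNF-α and 0.0417 (SE 0.010) without it, and genes matched in GC content by 0.01764 (SE 0.0069) and 0.0470 (SE 0.0067), so neither bias accounts for list means near 0.3. The per-library list means were apart by 0.2295 with and 0.270 without TNF-α. With an estimated correlation the adjusted p was 0.0581 without and 0.0727 with TNF-α, and by fry 8.8e-06 and 7.7e-06. Averaged per group, the per-library list means differed by 0.2987 (SE 0.016) without and 0.3079 (SE 0.042) with TNF-α. These values, the gaps and fry argue against variation of the whole gene family between these libraries. Camera with an estimated correlation, which compares the list with the other genes, did not pass. Variation between cultures stays open, since the labels do not say that the libraries came from separate cultures.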

How the results depend on the processing

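With 3 libraries per group, small differences of response were mostly out of reach, so a gene without a call is not shown to be unchanged. Leaving out the libraries with the highest mitochondrial share (TNF replicate 2 and MoCe_TNF replicate 3), restricting the slope to called genes, and the other tests of single lists were chosen after seeing the data. Of the comparisons for 322 gene results, 3548 were the same, 147 weaker, 7 stronger and 27 reversed. For 77 list results 634 were the same and 48 weaker. The cause of these changes was not tested.

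A 2-fold minimum left 296 genes for TNF against PBS, 395 for MoCe against PBS, 509 for MoCe_TNF against TNF, 193 for MoCe_TNF against MoCe and 8 for the interaction. Fry called 37, 33, 35, 30 and 18 lists in the same order (camera 20, 15, 13, 18 and 11), and camera with an estimated correlation called 2 for the interaction. The interaction had 55 genes, 144 with the DESeq2 Wald test (55 shared), 36 with limma on TPM (26 shared) and 32 without the high-mitochondrial libraries (24 shared). Without a filter on low counts the slope of the TNF-α responses fell to 0.116 from 0.448, their correlation to 0.122 from 0.4785 and that of the material effects to 0.2101 from 0.6365. With called genes only the slope was 0.7108 and the correlation 0.8098.

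With the replicate number as a block the interaction had 30 genes, all among the 55. STAT2 (adjusted p = 0.122), ADI1, CRYZ, HPGD, IRF7, ISG15, WARS, CD74 and GBP4 lost their calls, CCL20 gained one in MoCe_TNF against TNF (adjusted p = 0.0474), and IL6 had an interaction of -0.001755. Libraries of the same number did not pair: their deviations from the group means correlated at a mean of -0.0011 (-0.054 to 0.066, 18 pairs), and 4 of 12 libraries correlated best with the libraries of their own number.

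Leaving out each library gave 33 to 46 genes and 6 to 16 lists for the interaction, 0.3991 to 0.4476 for the correlation of the TNF-α responses and 0.5406 to 0.5784 for that of the material effects. The gene counts and both correlations all lay below the values from all 12 libraries (55, 0.4785 and 0.6365). The filter on low counts was applied anew each time, and its part in this was not tested. Genes without a call changed sign in TNF against PBS (IFI27 -0.04336 to 0.4212, IRF9 -0.01027 to 0.081), MoCe against PBS (NFKBIA -0.3634 to 0.02893, CXCL10 -0.7698 to 0.3868), MoCe_TNF against TNF (SOD2 -0.0009495 to 0.03188), MoCe_TNF against MoCe (IFIT1 -0.002237 to 0.07514, ISG15 -0.03935 to 0.05701, IRF9 -0.5409 to 0.5444) and the interaction (NFKBIA -0.133 to 0.2599, CCL20 -0.3035 to 0.1195, IL6 -0.1029 to 0.1169, IRF9 -0.5691 to 0.5164).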

Other observations

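The permutation tests of this part, and the estimated correlation for single lists, were chosen only after the result was seen. Within the proliferation genes, which fell as a list after pretreatment, mitotic genes and genes of DNA replication and the G1/S step moved apart. Of 23 mitotic genes 19 fell and 0 rose without TNF-α (mean log2 fold change -0.59, SE 0.060), and 20 fell and 0 rose with it (mean -0.59, SE 0.072). Of 19 replication and G1/S genes 3 fell and 3 rose without TNF-α (mean -0.02, SE 0.062), and 3 fell and 10 rose with it (mean 0.08, SE 0.079). Permuting the members between the 2 sets gave p = 2e-05 without and 1e-05 with TNF-α, the latter the smallest that 1e+05 permutations can give. These permutations take genes as independent, which genes regulated together are not, and the sets were formed after their members were seen to move apart, so the p-values do not test the separation. A candidate explanation is a smaller share of cells in mitosis, which these data do not measure directly.

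Genes of molybdenum cofactor enzymes and synthesis did not pass as a list with the material alone (mean 0.09, on the TPM scale -0.207, camera adjusted p = 0.916), yet single members of the 10 tested moved. Of all genes tested, 32.7% were called in this comparison. The xanthine dehydrogenase gene XDH fell by 0.61 (SE 0.10, edgeR adjusted p = 7.5e-04) and the cofactor sulfurase gene MOCOS fell by 0.25 (SE 0.06, adjusted p = 0.0062), while the aldehyde oxidase gene AOX1 rose by 1.48 (SE 0.32, edgeR adjusted p = 0.0047). With TNF-α present the values were -0.88, -0.35 and 1.21. IFNE, of 10 interferon genes the only 1 with enough counts to be tested (chromosome 9, 21480839 to 21482313), fell by 1.16 (SE 0.17, edgeR adjusted p = 4.3e-04) with the material alone and by 1.17 (SE 0.17) with TNF-α, from means of 1.92 and 2.03 CPM to 0.854 and 0.900 CPM. These genes were singled out after their values were seen.

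Some markers of other cell types also changed with the material alone, in both directions. Only 3 of 8 endothelial, 6 of 11 fibroblast, 2 of 8 melanocyte and 4 of 17 leukocyte markers had enough counts to be tested. Of the endothelial markers, too few for a list test, CDH5 rose from 3.74 to 18.9 CPM (2.335, SE 0.13, edgeR adjusted p = 3.6e-07) and VWF from 5.45 to 7.95 CPM (0.54, SE 0.13, adjusted p = 0.00999) in all 3 libraries, while ESAM did not pass. Of the fibroblast markers COL1A1 rose from 22.1 to 33.8 CPM (0.61, SE 0.07, adjusted p = 6.5e-05) and LUM from 0.848 to 1.62 CPM (0.93, SE 0.21, adjusted p = 0.0057), and PDGFRA from 0.072 to 0.249 CPM (1.75, SE 0.44, adjusted p = 0.011), though PDGFRA overlaps a gene on its strand. COL3A1, FBLN1 and MFAP5 did not pass, nor did the list (mean 0.77, on the TPM scale 0.374, camera adjusted p = 0.0575, 0.125 with an estimated correlation). The melanocyte marker MITF fell by 0.64 (SE 0.17, adjusted p = 0.015; 3.85 to 2.47 CPM), a call lost without MoCe replicate 1 (0.0543) or 3 (0.0587), and the leukocyte marker CD68 rose by 0.36 (SE 0.09, adjusted p = 0.012; 9.64 to 12.4 CPM). PMEL, CD3E, CD14 and ITGAM did not pass. With TNF-α present CDH5, VWF, COL1A1 and LUM passed again as higher, and MITF, CD68 and PDGFRA did not pass. CD14 fell by 0.51 (SE 0.15, adjusted p = 0.020) and ITGAM rose by 0.50 (SE 0.17, adjusted p = 0.041), calls lost without 4 of the 6 libraries for CD14 (TNF replicates 2 and 3, MoCe_TNF replicates 1 and 2; 0.0513 to 0.0679) and without each library but TNF replicate 2 for ITGAM (0.0648 to 0.143). HaCaT is a single cell line, so a change of state is a hypothesis that was not tested.

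A second hypothesis was that type I interferon-stimulated genes with the larger fall after pretreatment alone lose more of their TNF-α response. Across the 58 members the correlation was 0.1179 (permutation p = 0.377, adjusted p = 0.377) and the rank correlation 0.252 (p = 0.0564, adjusted p = 0.113). The 2 quantities share the PBS and MoCe libraries, which biases the correlation toward negative values, so the question stays open.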
